A study of Mus musculus with 4 samples.

How the data were processed

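Messenger RNA was profiled in primary tumour cells of a mouse model of pancreatic ductal adenocarcinoma, in which Cre recombinase driven from the Ptf1a locus activates an oncogenic Kras allele and deletes p53. Per the labels' protocols, cells received vehicle (a cyclodextrin solution), 100 nM JQ1, 2000 nM SAHA, or 100 nM JQ1 with 1000 nM SAHA for 6 hours. The source labels speak of treated mice, while the treatment protocol and the design text speak of treated cells, which is followed here. Each condition was read on 1 array, so the series holds 4 arrays and no replicates. Total RNA was extracted on columns, checked on a Bioanalyser, and 250 ng of it was amplified and biotin-labelled with an oligo-dT-primed in vitro transcription kit, per the labels' protocols. Such labelling reads the 3' ends of polyadenylated transcripts.

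The values deposited by the authors are log2 expression values per probe set and array. RMA and Affymetrix Expression Console are named in the submitters' processing notes, without versions. RMA subtracts a modelled background, makes the arrays' distributions alike and summarises the probes of a set on the log2 scale, so a change common to nearly all transcripts of a sample would be removed. The scale and centring of the deposited table are not stated in it: the log2 scale was taken from the naming of RMA and from the range of values, 2.62 to 14.3. The values are uncentred signal levels, so a ratio's direction follows from the column labels. The arrays had medians of 4.51 for vehicle, 4.51 for JQ1, 4.52 for SAHA and 4.51 for JQ1 with SAHA.

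The table held 45141 rows, of which 104 were control probe sets. Genes were named from the platform annotation held by GEO, dated 2016: 28898 probe sets name 1 gene, 551 name several and 15588 are not listed with a gene. For 28689 of the probe sets naming 1 gene the Entrez identifier was also found in a RefSeq gene table, whose symbols were used; 0 symbols needed an update. Only probe sets naming 1 gene were used, which covered 17097 genes. Each gene was represented by its probe set with the highest mean over the 4 arrays. A gene entered the comparisons if at least 1 array reached the median of all values of non-control probe sets, a log2 value of 4.51, called the signal floor here; 10641 genes did. The floor is a convention and no measured background: the background probe sets had medians between 3.27 and 3.37. A ratio with 1 value under the floor is less certain in size.

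Ratios are differences of log2 values. With 1 array per condition no spread within a condition can be estimated, so no difference between conditions was tested and no p-value is given, and genes were counted by size alone, at 2-fold or more in either direction. Named genes were chosen by a rule. It took the 10 highest and the 10 lowest ratios for each treatment against vehicle. It took the 5 highest and 5 lowest for the combination against each single compound and for the difference from the sum of the single-compound ratios. It added up to 4 members of each gene list with the largest ratios, and all genes of a short list fixed by name; predicted genes known only by clone or model names were counted but passed over. The rule, the counts, the alternatives and 41 gene lists covering chromatin regulators, known responses to these drug classes, cell cycle, signalling, death, stress, metabolism and cell types were fixed before the data were examined. For each list the median ratio was computed, and members at least 1.5-fold higher or lower were counted. For the 34 lists with at least 5 measured genes the median was placed among 10000 random lists of the same size matched on mean expression in 20 bins. That percentile describes these arrays and is not a test; it was computed in 6 comparisons.

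The pairs JQ1 against vehicle and combination against SAHA share no array, nor do SAHA against vehicle and combination against JQ1, so overlaps between such pairs are free of shared array noise. For JQ1 and SAHA against the same vehicle array, 100 simulations of unchanged groups sharing 1 array gave the overlap and covariance that the sharing produces when no gene differs. Where genes do differ, noise of the shared array can carry more of them past 2-fold in both ratios. The simulated overlap is therefore no upper bound for these data. Independent lists would overlap by the product of their sizes over the number of genes, which is printed beside each overlap.

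Alternatives were no floor, a floor at the 75th percentile, a floor on the mean of the arrays, the mean of a gene's probe sets, leaving out probe sets with _s_at or _x_at names (which can match several transcripts), only genes with at least 2 probe sets going the same way, thresholds of 1.5-fold and 3-fold, and median centring, quantile normalization or cyclic loess on the deposited values. For agreeing probe sets, a gene with at least 2 probe sets past the floor took their mean. It entered only those comparisons in which all of them had the same sign. The number of such genes therefore differs by comparison, and genes with ratios near 0 are left out more often. The procedure was run on simulated data for JQ1 against vehicle with 10250 genes. Of 100 genes planted at 4-fold, 98 were recovered, of 100 planted at 2.83-fold, 95 were recovered, and 0 unchanged genes were called. The genes missed were those that fell under the floor. The simulated noise was smaller than the upper bound on 1 array's error in these data, an SD of 0.23 log2 units. The run therefore checks the procedure and gives no rate of false calls for these arrays. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used, and R 4.3.3 with limma 3.58.1 for cyclic loess.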

Results

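Gene expression was compared in primary mouse pancreatic ductal adenocarcinoma cells after 6 hours with vehicle, JQ1, SAHA or both compounds. JQ1 displaces the BET proteins Brd2, Brd3 and Brd4 from acetylated histones, and SAHA (vorinostat) inhibits histone deacetylases. The design asks which transcripts differ under either compound and which under the pair. There was 1 array per condition and no replicate, so each ratio below compares 2 arrays and its error across cultures is unknown. The number of arrays, 4, limits the precision. The signal floor was reached by 10001 genes in the vehicle array, 10017 in the JQ1 array, 10074 in the SAHA array and 10088 in the combination array. Signals of the 3' probe sets of Actb exceeded those of its 5' probe sets by 0.28, 0.25, 0.23 and 0.20 log2 units in the same order, a measure of RNA integrity and labelling. Hybridisation spikes, 18 probe sets added in equal amount to each array, had log2 ratios with an SD between 0.055 and 0.112 in the 5 comparisons, and the largest single ratio was 0.40. Poly-A spikes, 24 probe sets added to the RNA before labelling, varied more, with an SD between 0.111 and 0.185, a largest single ratio of 0.69 and a median of 0.22 in the combination against SAHA. If errors are independent and alike in the 4 arrays, the SD of a ratio's error averaged over genes is at most 0.33. Over all probe sets the arrays correlated with r between 0.967 (vehicle and combination) and 0.988 (JQ1 and combination).

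**Figure D1:**
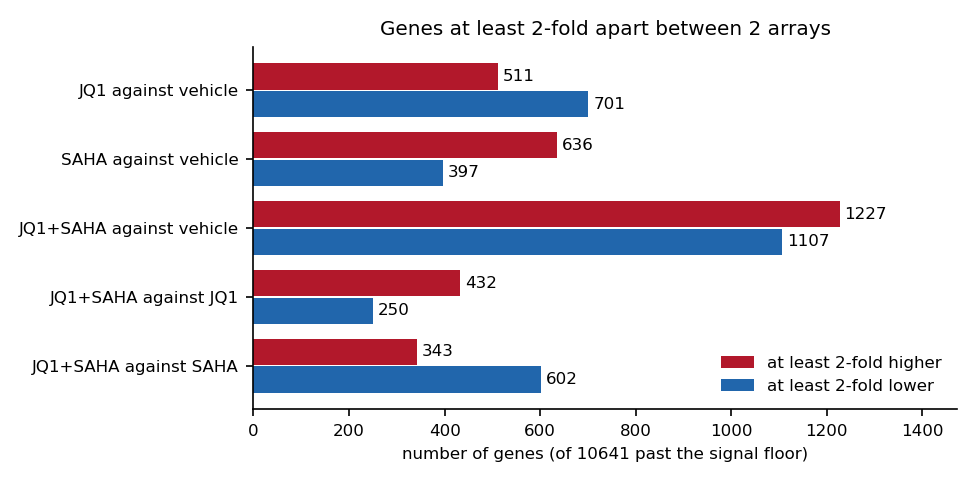
Number of genes (horizontal axis) at least 2-fold higher (red) or lower (blue) in the first array than in the second, for 5 comparisons of 2 arrays each. The combination against vehicle has the longest bars, 1227 higher and 1107 lower, and the bars start at 0.

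JQ1 against vehicle: histone genes held the first 6 places among the named genes higher with JQ1. H2bu2 was 15.1-fold higher in the JQ1 array (log2 ratio 3.91), H2bc21 13.9-fold, H2aw 13.4-fold, the linker histone H1f2 12.3-fold and H3c15 12.1-fold higher. Histone genes of one class have similar sequences, so probe sets may read more than 1 of them and the identity of single histone genes is uncertain. Labelling was oligo-dT primed, so histone ratios here and below cover polyadenylated transcripts only and not all histone mRNA. Btc, which encodes the EGF receptor ligand betacellulin, was 41.8-fold lower (log2 ratio -5.39). The phosphatase gene Ptpn22 followed at 31.5-fold lower, Ccbe1, needed for lymphatic vessel growth, at 22.3-fold lower, and Tns4, which encodes a focal adhesion tensin, at 20.9-fold lower. Altogether 511 genes were at least 2-fold higher and 701 at least 2-fold lower.

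Other genes at the top for JQ1 were H4bc24 (an alias of a histone H2b gene) at a log2 ratio of 3.28, Fam117a at 3.13, the hypoxia-inducible factor gene Epas1 at 2.91, the growth factor receptor gene Fgfr2 at 2.91 and the polysialyltransferase gene St8sia4 at 2.89. At the bottom, Il18rap, an interleukin receptor chain, stood at -4.20, the hyaluronan synthase gene Has2 at -4.19, the Fos-family gene Fosl1 at -4.18, Pbp2 at -3.87, Mab21l4 at -3.87 and Exoc3l4 at -3.65. Under the signal floor lay Btc, Ptpn22 and Has2 in the JQ1 array, at 4.43, 3.85 and 4.26, and H4bc24 and St8sia4 in the vehicle array, at 3.95 and 4.14, so the size of these ratios is less certain. Fgfr2 depended on the probe set, with 0.54 without probe sets of shared-transcript names and 1.19 as the mean of all its probe sets. As the mean of probe sets Epas1 stood at 1.65, St8sia4 at 1.63, Ccbe1 at -2.06, Btc at -4.32, Il18rap at -3.44 and Fosl1 at -3.42.

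All 13 genes of the list of BET inhibitor induced genes were at least 1.5-fold higher with JQ1, with a median log2 ratio of 1.77, above all 10000 matched random lists. Hexim1, which sequesters the elongation factor P-TEFb, was 4.44-fold higher, Serpini1 4.62-fold (log2 ratio 2.21, or 1.26 as the mean of its probe sets) and Klhl24 6.13-fold higher. Of 13 measured histone genes 10 were higher and 0 lower, with a median of 1.47, above all random lists; 3 of them, H1f2, H2bc21 and H2bc4, are also in the previous list. Among genes with at least 2 agreeing probe sets the histone median was 0.71. Of the BET genes themselves, Brd2 was 3.42-fold higher and Brd3 stood at 0.09, or 0.44 as the mean of its probe sets, while Brd4 was not analysed here.

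Myc, its targets and outputs of ERK signalling were lower in the JQ1 array. Myc was 3.69-fold lower (log2 ratio -1.88), and of 51 measured genes of the MYC target list, which holds Myc itself, 32 were at least 1.5-fold lower and 0 higher, with a median of -0.82, below all random lists. Srm, which encodes spermidine synthase, stood at -1.78 and Polr1b, a subunit of RNA polymerase I, at -1.67. Of 36 ribosome biogenesis genes 23 were lower and 0 higher, with a median of -0.74 and the snoRNP genes Gar1 at -1.78 and Dkc1 at -1.68. Of 22 output genes of ERK signalling 17 were lower and 0 higher, with a median of -1.14; after Fosl1 came Ereg at -2.88, Dusp6 at -2.34 and Spry4, under the floor with JQ1, at -2.09. Both medians lay below all random lists. Among G1 regulators 3 of 11 were lower, led by Ccnd1 (cyclin D) at -1.57, and the median of -0.41 lay at percentile 1.35.

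Inflammatory and anti-apoptotic lists had medians below 0 with JQ1, and stress lists medians above 0. Of 36 NF-kB and inflammatory genes 17 were lower and 6 higher, with a median of -0.37 (percentile 0.05) that was 0.09 under the stricter floor; Mmp13 stood at -2.46, Csf2 at -2.35, Il33 at -2.22 and Ptgs2, a prostaglandin synthase gene, at -2.03. Of 20 interferon-stimulated genes 9 were lower and 2 higher, with a median of -0.56 (percentile 0.02). Over those with agreeing probe sets, at most 3 genes, it was 0.09. Rtp4 stood at -2.29 and Ifit3 at -1.73. Mmp13, Csf2, Rtp4 and Ifit3 were under the floor with JQ1. Of 10 anti-apoptotic genes 5 were lower and 0 higher, with a median of -0.58 (percentile 0.13) that was -0.27 without a floor and -0.29 with the mean of probe sets; Bcl2 stood at -1.49, or -0.93 as the mean of its probe sets, and Birc3 at -1.23. Of 27 genes of the unfolded protein and amino acid response 13 were higher and 0 lower, with a median of 0.55, above all random lists, and Atf3 and Ddit3, both stress transcription factors, at 2.58 and 2.32. The list of metallothionein and oxidative stress genes had a median of 0.39 (percentile 99.6), or 0.22 among genes with agreeing probe sets, led by Gclc, which serves glutathione synthesis, at 1.85 and Hmox1 at 1.61. Antigen presentation genes had a median of 0.46 (percentile 99.4), or 0.098 without a floor, with H2-K1 at 1.26.

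SAHA against vehicle: of the 10 genes with the highest ratios, Fam117a and St8sia4 were also among the 10 highest for JQ1. Fam117a was 13.6-fold higher in the SAHA array (log2 ratio 3.77), St8sia4 13.1-fold and Cidea, which encodes a lipid droplet protein, 11.2-fold higher. Tspyl4 stood at 3.59 and the receptor tyrosine kinase gene Erbb3 at 3.46. Smco4 was 7.65-fold lower (log2 ratio -2.94), the metalloprotease gene Adam12 7.35-fold lower and Nbn, a member of a DNA break repair complex, 5.54-fold lower. In total 636 genes were at least 2-fold higher and 397 at least 2-fold lower.

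Next in the SAHA ranking came the mitochondrial arginase gene Arg2 at 3.40, Sgtb at 3.40, Castor2 at 3.27, Gpt2, an alanine aminotransferase gene, at 3.16 and the profilin gene Pfn2 at 2.97. On the lower side were Casd1 at -2.36, Mab21l4 at -2.30, Rtp4 at -2.23, Nexn, which encodes an actin-binding protein, at -2.21, Borcs7 at -2.18, Dynap at -2.16 and Ube2cbp at -2.15. Under the signal floor lay Arg2, St8sia4 and Cidea in the vehicle array, at 3.51, 4.14 and 4.49, and Rtp4 in the SAHA array, at 4.08. As the mean of all probe sets Erbb3 stood at 1.64, Castor2 at 1.74, Gpt2 at 1.97, St8sia4 at 2.26, Adam12 at -2.19, Casd1 at -1.50, Borcs7 at -1.32 and Rtp4 at -1.18.

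Of 19 HDAC inhibitor induced genes 8 were at least 1.5-fold higher and 1 lower with SAHA, with a median of 0.48 (percentile 99.9); Glrx (glutaredoxin) was 3.27-fold higher and Gsn, the actin-severing protein gelsolin, 2.61-fold higher. Of the 13 BET inhibitor induced genes 9 were higher, with a median of 0.78, above all random lists, although Hexim1 stood at 0.20, or 0.41 as the mean of its probe sets. The 2 lists share 3 measured genes, H2bc4, Sat1 and Txnip, so they are not separate results. Histone genes had a median of 0.16 (percentile 84.9), with H2bu2 at 2.02. Hdac5 was 3.44-fold and Hdac11, under the floor with vehicle, 2.66-fold higher among 9 measured HDAC genes. Their median was 0.44 (percentile 97.0) but -0.56 over those with agreeing probe sets, at most 2 genes. Hdac1 and Hdac2 stood at 0.52 and -0.17, with Hdac2 at -0.44 as the mean of its probe sets.

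Lists of MYC targets, ribosome biogenesis, S phase and mitosis had medians below 0 in the SAHA array. Myc stood at -0.96; 19 of 51 MYC targets were lower and 2 higher, with a median of -0.47, and 15 of 36 ribosome biogenesis genes were lower and 0 higher, with a median of -0.49. S phase genes had a median of -0.34, led by Tk1 (thymidine kinase) at -1.68, and mitosis genes a median of -0.34, led by Cdc20 at -1.19 and Kif23 at -1.16. These 4 medians lay below all random lists. Interferon-stimulated genes had a median of -0.53 (percentile 0.01), with 10 of 20 lower, Ifih1 at -2.14 and Ifit3, under the floor with SAHA, at -1.78. The median was -0.24 with the floor on the mean of the arrays. Over those with agreeing probe sets, at most 3 genes, it was -0.06. YAP targets had a median of -0.32 (percentile 0.55), with Ajuba at -1.02 and Gadd45a at 1.41.

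ERK output genes showed no common direction with SAHA: 5 of 22 were higher and 5 lower, with a median of 0.04 (percentile 52.6), and Etv1 stood at 2.64. Of 20 immediate early genes 10 were higher and 0 lower, with a median of 0.57 (percentile above 99.9), or 0.38 with the mean of probe sets, Atf3 at 1.87 and Klf2 at 1.46. Of 16 pro-apoptotic genes 8 were higher and 2 lower, with a median of 0.58 (percentile 99.9); Bcl2l11, which encodes the BH3-only protein Bim, was 3.11-fold higher and Casp9 2.35-fold higher. The unfolded protein and amino acid response had a median of 0.41, with Chac1, a glutathione-degrading enzyme gene, at 2.54. Cholesterol synthesis genes had a median of 0.44 (percentile 98.8) with Mvd at 1.35, glycolysis and hypoxia genes one of 0.31 (percentile 99.1), or 0.096 among genes with agreeing probe sets, with Bnip3 at 2.04 and Adm at 1.98, and neuronal genes one of 0.36 (percentile 98.7), or 0.20 without a floor, with Rab3a, under the floor with vehicle, at 1.43. The cytoskeletal gene Acta2 was 3.19-fold lower, at a signal of 9.37 against 11.05 with vehicle.

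**Figure D2:**
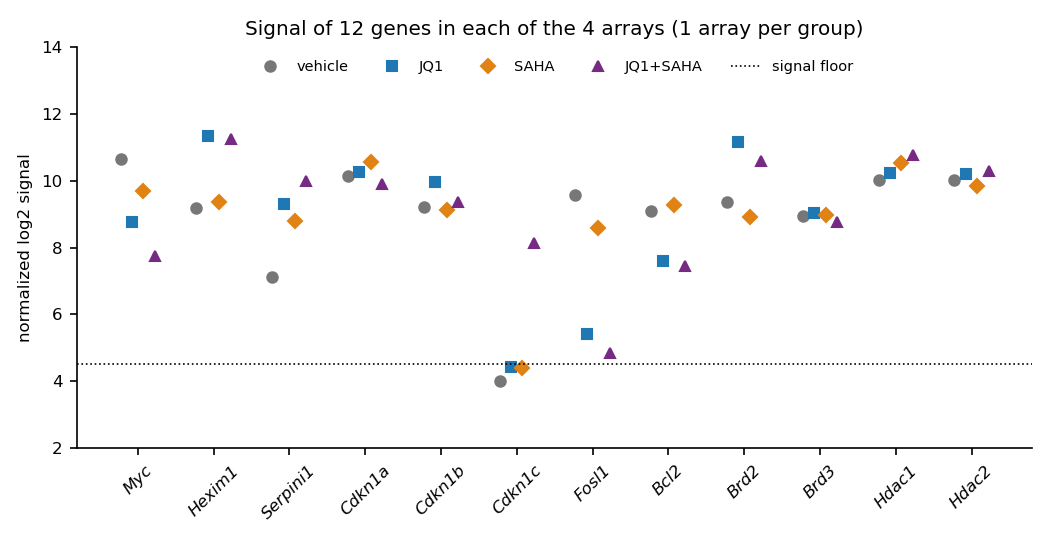
Normalized log2 signal (vertical axis) of 12 genes fixed by name, with 1 symbol per array: vehicle (grey circles), JQ1 (blue squares), SAHA (orange diamonds) and the combination (purple triangles); the dotted line is the signal floor. Myc is highest with vehicle, at 10.66, and lowest with the combination, at 7.75, while Cdkn1c is above the floor in the combination array alone, at 8.13.

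JQ1 with SAHA against vehicle: this comparison had the most genes past 2-fold, 1227 higher and 1107 lower. Fam117a was 29.2-fold higher (log2 ratio 4.87), Acss2, which makes acetyl-CoA from acetate, 27.2-fold and Nrip3 25.8-fold higher. The serine protease gene Prss16 stood at 4.81. Cdkn1c, which encodes an inhibitor of cyclin-dependent kinases, was 17.4-fold higher. Mab21l4 was 58.5-fold lower (log2 ratio -5.87), Ccbe1 33.9-fold, Tns4 32.7-fold, Ptpn22 28.1-fold, Fosl1 26.6-fold and Btc 26.5-fold lower. H2bc21 stood at 4.40, H2bu2 at 4.33, St8sia4 at 4.18, Tspyl4 at 4.17 and H1f2 at 4.08 on the higher side, and Dynap at -4.47, the tight junction gene Cldn2 at -4.42, Il18rap at -4.37 and the tryptase gene Prss22 at -4.33 on the lower side. Under the signal floor lay Nrip3, Cdkn1c and St8sia4 in the vehicle array, at 3.6, 4.01 and 4.14, and Mab21l4, Ptpn22 and Dynap in the combination array, at 3.84, 4.02 and 4.40. As the mean of probe sets St8sia4 stood at 2.46, Nrip3 at 3.27, Ccbe1 at -2.36, Fosl1 at -3.67, Btc at -3.89, Cldn2 at -3.43 and Il18rap at -3.70.

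ERK output genes had the lowest median of the 34 lists in the combination array. Of 22, 19 were at least 1.5-fold lower and 1 higher, with a median of -2.07, below all random lists, against -1.14 with JQ1 and 0.04 with SAHA. Ereg, an EGF receptor ligand, was 19.2-fold lower and the ERK phosphatase gene Dusp6 11.4-fold lower; among genes with agreeing probe sets the median was -1.28. Anti-apoptotic genes had a median of -1.24, below all random lists, or -0.64 with the mean of probe sets; Cflar, an inhibitor of death receptor signalling, was 6.49-fold lower, Bcl2l1 (Bcl-xL) 3.75-fold lower and Bcl2 3.10-fold lower. Pro-apoptotic genes went both ways, with 8 of 16 higher and 3 lower and a median of 0.52 (percentile 98.3): Bcl2l11 was 3.46-fold higher, while Casp8, the initiator caspase of death receptors, was 5.34-fold lower and Bak1 4.19-fold lower.

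Myc was 7.49-fold lower in the combination array, and 31 of 51 MYC targets were lower and 0 higher, with a median of -0.67; Utp20 stood at -2.05 and Srm at -2.01. Of 36 ribosome biogenesis genes 20 were lower and 0 higher, with a median of -0.72 and Dkc1 at -2.26. Of 18 YAP targets 11 were lower and 2 higher, with a median of -0.81, or -0.47 with the mean of probe sets; F3 (tissue factor) stood at -2.98 and Ankrd1 at -2.06. These 3 medians lay below all random lists. Interferon-stimulated genes had a median of -0.71 (percentile 0.01), which was 0.04 under the stricter floor; Ifih1 stood at -1.93 and Cxcl10 at 2.01. Mitosis genes had a median of -0.30 (percentile 0.40) with Plk1 at -1.35. Among 11 G1 regulators cyclin gene Ccnd1 was at -2.87 and Cdk6 at -2.05, with 5 lower and 1 higher. The median of these regulators was -0.16 (percentile 20.55), or -0.86 among genes with agreeing probe sets. Epithelial genes had a median of -0.32 (percentile 0.57), or -0.18 among genes with agreeing probe sets, with Lamb3 at -2.25 and Cdh1 (E-cadherin) at -1.36, and mesenchymal genes one of -0.50 (percentile 0.15), or -0.14 without a floor, with Itga5, under the floor in the combination array, at -1.65.

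All 13 BET inhibitor induced genes were at least 2-fold higher in the combination array, with a median of 2.06, and 9 of 13 histone genes were at least 1.5-fold higher, with a median of 1.52, or 0.70 among genes with agreeing probe sets. HDAC inhibitor induced genes had a median of 1.14, with 13 of 19 higher, against 0.51 with JQ1 and 0.48 with SAHA. These 3 medians lay above all random lists. Of 18 cholesterol synthesis genes 11 were higher and 0 lower, with a median of 0.88 and Mvd and Idi1 at 1.74 and 1.61. Of 18 neuronal genes 10 were higher and 1 lower, with a median of 0.84, or 0.37 without a floor, and Bex1 at 1.85. Both medians lay above percentile 99.9. Heat shock genes had a median of 0.44 (percentile 99.6), or 0.22 among genes with agreeing probe sets, with Hspa1b at 2.62 and Hspb1 at 2.21, and Atf3 stood at 3.48. Among HDAC genes Hdac5 was 5.28-fold and Hdac11, under the floor with vehicle, 4.74-fold higher, and Hdac7 5.83-fold lower.

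**Figure D3:**
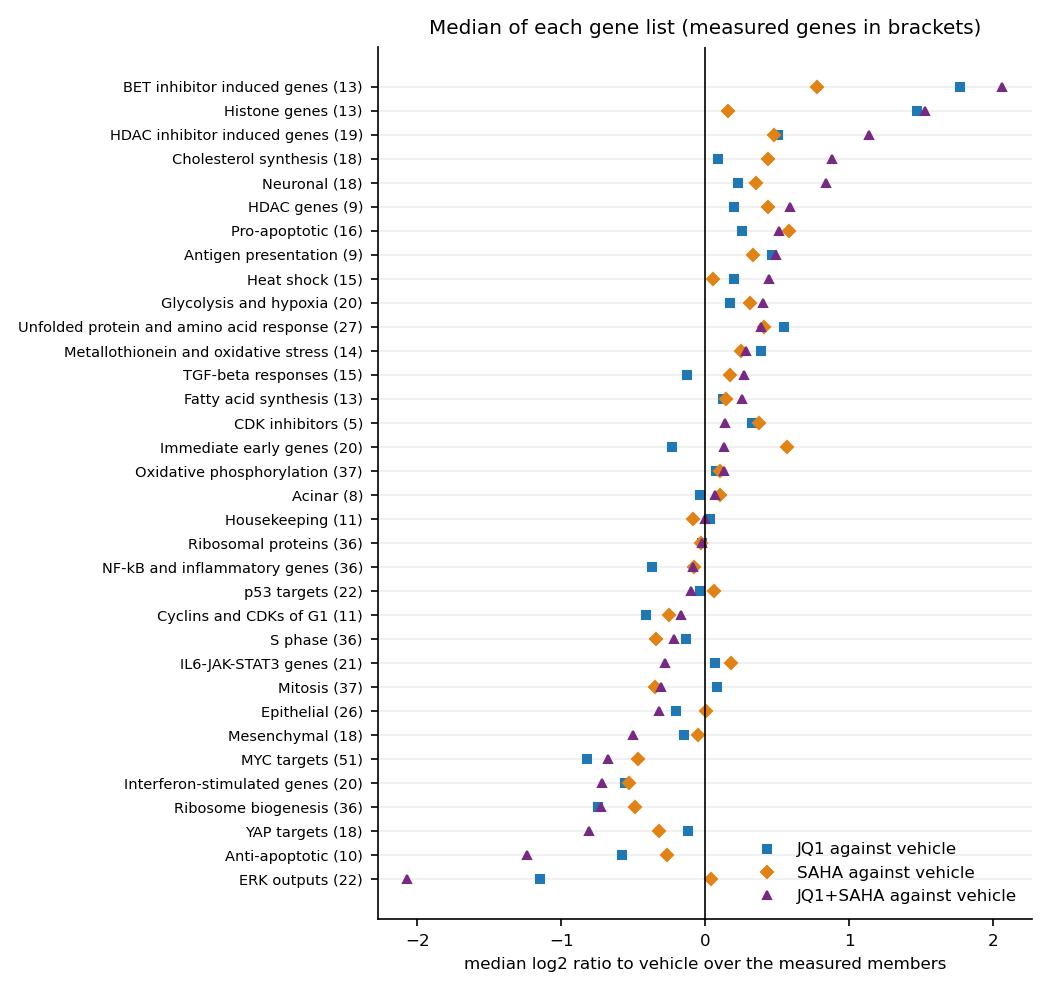
Median log2 ratio to vehicle (horizontal axis) over the measured genes of each of the 34 lists with at least 5 of them, for JQ1 (blue squares), SAHA (orange diamonds) and the combination (purple triangles), ordered by the combination. ERK outputs lie at -1.14, 0.04 and -2.07, and BET inhibitor induced genes at 1.77, 0.78 and 2.06; no error is drawn because each median comes from 1 ratio of 2 arrays.

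Adding 1000 nM SAHA to JQ1 gave 432 genes at least 2-fold higher and 250 at least 2-fold lower in the combination array than in the JQ1 array, but 78 and 77 among genes with agreeing probe sets and 238 and 205 under the stricter floor. Cdkn1c was 12.9-fold higher (log2 ratio 3.69), Rundc3b 9.60-fold, the kinesin gene Kif5c 8.20-fold, Plat, which encodes tissue plasminogen activator, 7.70-fold and Rab40b 7.38-fold higher. Mmp14, a membrane-bound matrix metalloproteinase gene, was 6.14-fold lower (log2 ratio -2.62), the microRNA host gene Mir100hg 6.08-fold, Cyp1b1, which encodes a monooxygenase, 5.83-fold, Tmie 4.87-fold and the forkhead gene Foxq1 4.80-fold lower. As the mean of probe sets Kif5c stood at 1.65, Plat at 2.31, Rab40b at 1.77, Mmp14 at -1.77 and Tmie at -1.14, and without probe sets of shared-transcript names Foxq1 stood at -1.15. Cdkn1c and Rab40b were under the floor with JQ1, and Tmie in the combination array.

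Cholesterol synthesis genes were higher in the combination than in the JQ1 array, 10 of 18 by 1.5-fold and 0 lower, with a median of 0.79, above all random lists, or 0.50 with the mean of probe sets; Mvd stood at 1.59 and Fdft1 at 1.35. ERK outputs were lower still, 11 of 22 with a median of -0.61, or -0.23 among genes with agreeing probe sets; Plaur, the urokinase receptor gene, stood at -1.56 and Ccnd1 at -1.30. Mitosis genes had a median of -0.39 and YAP targets one of -0.39, both, like that of ERK outputs, below all random lists. Anti-apoptotic genes had a median of -0.49 (percentile 0.11) with Cflar at -1.61, and mesenchymal genes one of -0.31 (percentile 0.06); without a floor the medians were -0.23 and -0.17. HDAC genes had a median of 0.50 (percentile 99.1) that was -0.52 over those with agreeing probe sets, at most 2 genes. MYC targets had a median of 0.03 (percentile 53.3), with 3 of 51 lower and 1 higher, although Myc itself was 2.03-fold lower; ribosome biogenesis genes had a median of 0.05 (percentile 67.9). Among genes with agreeing probe sets the 2 medians were -0.12 and 0.20.

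Against the SAHA array the combination had 343 genes at least 2-fold higher and 602 at least 2-fold lower; this pair adds JQ1 but also lowers SAHA from 2000 to 1000 nM. H2bc21 was 14.2-fold higher (log2 ratio 3.83), Cdkn1c, under the floor with SAHA, 13.4-fold, H1f2 12.3-fold, Nrip3 9.49-fold and the chemokine gene Cxcl10 8.83-fold higher. Btc was 17.9-fold lower (log2 ratio -4.16), Cldn2 17.8-fold, Dusp6 13.8-fold, Sdcbp2 13.8-fold and Fosl1 13.2-fold lower; as the mean of probe sets Nrip3 stood at 2.6, Btc at -3.03, Cldn2 at -3.08 and Fosl1 at -2.75. All 22 ERK outputs were at least 1.5-fold lower, with a median of -1.89, below all random lists. Histone genes had a median of 2.05, or 0.52 among genes with agreeing probe sets, and BET inhibitor induced genes one of 1.03, or 0.60 with the mean of probe sets, both above all random lists. MYC targets stood at -0.24 (percentile 0.01) and anti-apoptotic genes at -0.74 (percentile 0.01), or -0.34 with the mean of probe sets. Immediate early genes had a median of -0.38 (percentile 0.10) with Egr1 at -2.08, and 0.48 among genes with agreeing probe sets. HDAC inhibitor induced genes stood at 0.34 (percentile 99.9), or -0.30 among such genes, and fatty acid synthesis genes at 0.28 (percentile 98.1), or -0.03. Csf2 stood at -3.70 and Ptgs2 at -3.41 among 36 NF-kB and inflammatory genes. Of these 16 were lower and 7 higher, with a median of -0.05 (percentile 28.3).

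The ratio of JQ1 to vehicle and that of the combination to SAHA share no array and both add JQ1, but the second also lowers SAHA from 2000 to 1000 nM. In both, 178 genes were at least 2-fold higher and 363 at least 2-fold lower, where independent lists would share 16.5 and 39.7. Of the 511 genes higher with JQ1 alone, 95.3% were also higher in the second pair by any amount, and of the 701 lower genes 96.9% were also lower; across genes, which are not independent replicates, r was 0.74. For SAHA the pairs were SAHA against vehicle, at 2000 nM, and the combination against JQ1, at 1000 nM, so neither set of pairs repeats 1 contrast exactly. Here 226 genes were higher and 87 lower in both, where independent lists would share 25.8 and 9.33, and r across genes was 0.67. Btc, Fosl1, Ccbe1, Tns4, H2bc21 and H1f2 were past 2-fold in both JQ1 pairs, and Plat, Kif5c, Pfn2, Fam117a and Erbb3 in both SAHA pairs.

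**Figure D4:**
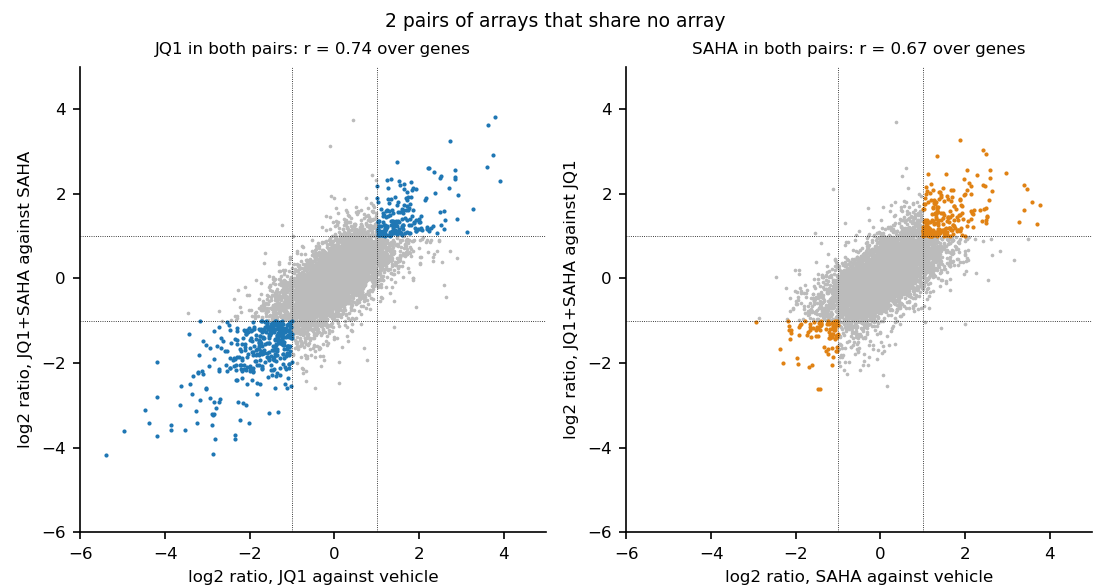
Log2 ratios of 10641 genes in 2 pairs of arrays that share no array, for JQ1 (left, JQ1 against vehicle on the horizontal axis and combination against SAHA on the vertical axis) and for SAHA (right, SAHA against vehicle and combination against JQ1). Each point is a gene, dotted lines mark 2-fold, and coloured points are past 2-fold the same way in both pairs, 541 genes on the left and 313 on the right.

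JQ1 and SAHA shared part of their genes. Fam117a, St8sia4, Tspyl4 and Sgtb were at least 2-fold higher with each compound, and Mab21l4, Ccbe1, Adam12, Smco4 and Has2 at least 2-fold lower with each. In all, 198 genes were higher and 177 lower with both, where independent lists would share 30.5 and 26.2. Both ratios use the same vehicle array, and simulated unchanged groups sharing 1 array gave 12.2 higher and 8.56 lower genes. These simulated counts hold no genes that differ and lie below those of independent lists. They do not give the overlap that the sharing adds in these data. The covariance across genes was 0.209 against 0.0539 in the simulation. The correlation was 0.505 against 0.499, but the simulated value follows from the sharing of 1 array whatever the noise. The 2 correlations therefore decide nothing. The mean covariance of 4 pairs of ratios that share 1 array each, in which array errors of equal size cancel, was 0.109. The vehicle is a single array and cannot be split, so part of the excess may come from the shared control.

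The combination lay at least 2-fold above the sum of the single-compound log2 ratios for 214 genes and at least 2-fold below it for 244, of 10641. The combination held a lower SAHA dose than SAHA alone, so the sum is a reference for description and no prediction of additive action. Furthest above were Cdkn1c by 3.32, Cxcl10 by 3.26, the deoxycytidylate deaminase gene Dctd by 2.63, Nbn by 2.50 and Ung, which encodes a uracil-DNA glycosylase, by 2.22. Cdkn1c read 4.01 with vehicle, 4.44 with JQ1 and 4.38 with SAHA, all under the floor, and 8.13 with the combination; it rests on 1 probe set. Furthest below were Vldlr, a lipoprotein receptor gene, at -3.08, Gpt2 at -2.73, Cyp1b1 at -2.70, the stress regulator gene Nupr1 at -2.61 and Chac1 at -2.57. Gpt2 stood at -1.42 without probe sets of shared-transcript names and at -1.70 as the mean of all, and Vldlr at -2.18 as the mean. Of other CDK inhibitor genes, in the combination against vehicle, Cdkn1a stood at -0.24 and Cdkn1b at 0.14. The median of the 5 measured CDK inhibitor genes, Cdkn1c included, was 0.14 (percentile 59.0). With the mean of probe sets Cdkn1b and the median stood at -0.14.

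The 36 ribosomal protein genes had medians of -0.02, -0.03 and -0.02 for JQ1, SAHA and the combination against vehicle, and 11 housekeeping genes 0.03, -0.08 and 0.00. Among genes with agreeing probe sets the medians were -0.12, -0.14 and -0.15 for the first list and -0.30, -0.38 and -0.37 for the second. They rest on at most 15 and 6 genes, and that alternative leaves out genes with ratios near 0 more often. In the reported values all 11 housekeeping genes lay within 1.5-fold of vehicle with each treatment, as did at least 35 of the 36 ribosomal protein genes. Il6 and Ptf1a stayed under the signal floor in all 4 arrays. Brd4, Hdac3, Kras, Trp53 and H1f0, fixed by name beforehand, had no probe set naming them alone and were not analysed here.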

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

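Of the tests below, the reading of the shared genes against the JQ1 array, the comparison of single-array counts, the floor test of MYC targets, both readings of the spikes and that of the Cdkn1c neighbours against JQ1 were chosen only after related results were seen; for the normalization test of MYC targets the median as reported had been seen, but no value under another normalization.

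A few genes went in opposite directions when a compound was given alone and beside the other one; each effect is 1 ratio of 2 arrays, so these differences were not tested. JQ1 had 2 such genes past 2-fold in both pairs. The second ratio minus the first was -2.57 for Chac1, higher with JQ1 alone, and 2.50 for Nbn, lower with JQ1 alone. By arithmetic this difference equals the distance from the sum of the single-compound ratios given above, for JQ1 and for SAHA alike. These values therefore repeat that result and are no separate observation. The second JQ1 pair also lowers SAHA from 2000 to 1000 nM, and SAHA alone gave 2.54 for Chac1 and -2.47 for Nbn, so the lower SAHA dose is not separated from JQ1 here. SAHA, at 2000 nM alone and 1000 nM beside JQ1, had 5: Cxcl10 at 3.26 and Dctd at 2.63, lower with SAHA alone, and Nupr1 at -2.61 and Vldlr at -3.08, higher with SAHA alone, as was Pik3r3, which the naming rule did not select and which was named after its values were seen (1.05 with SAHA alone, -1.03 beside JQ1). Probe sets without a single listed gene, which entered no comparison, also carried signal: 1197 of 7043 past the floor were at least 2-fold apart between the combination and vehicle, 541 higher and 656 lower.

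The 375 genes past 2-fold the same way with JQ1 and with SAHA could reflect noise of the shared vehicle array. That noise does not enter the combination's ratios to the single compounds, and there 331 of 375 members lay further in the shared direction against the JQ1 array (88.3%, exact 95% binomial interval 84.6 to 91.3) and 345 of 375 against the SAHA array (92.0%, 88.8 to 94.5). Noise of the vehicle array as the whole cause would give at most as many members in that direction as against it, so both values argue against it; the intervals treat genes as independent. A shared part of the responses to BET and HDAC inhibition remains a hypothesis. Differences between cultures that have no replicate here stay open.

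In the combination array 85 genes stood at least 2-fold above all 3 other arrays, led by Cdkn1c at 3.69 above the next array, Rab40b at 2.45, Prss16 at 2.45 and Acss2 at 2.07. Noise alike in every array cannot be told apart from an effect of the pair by this count: the vehicle array had 175 such genes, SAHA 51 and JQ1 19, but the design sets the vehicle apart from 3 treated arrays and keeps JQ1 close to the combination, the spread of such counts is unknown with 1 array each, and the bound fixed beforehand, on the highest count, was not passed. Other normalizations of values already normalized moved 0 of the 123 named ratios beyond the spread. The lowest for Cdkn1c against JQ1, 3.69, therefore decides nothing although it passes the bound set beforehand. The median ratio of all genes, 0.03, already left no room for a shift of all genes by that size. The 42 spikes, with JQ1 signals from 3.97 to 13.4, had a largest ratio of the same 2 arrays of 0.43. They argue only against a normalization shift common to probe sets of such signals. A change across the locus would raise its neighbours. Yet the 14 measured genes within 500 kb had a median ratio to vehicle of -0.059 (SD 0.76 over genes) and to JQ1 of 0.129 (SD 0.56). Of them 2, Phlda2 at 1.23 and Dhcr7 at 1.06 (named after their values were seen), were over 2-fold higher than with JQ1. Against vehicle Phlda2 stood at -3.21 with JQ1 and -1.98 with the combination, and Dhcr7 at -0.31 and 0.75. An effect of the pair on Cdkn1c is a hypothesis from 1 probe set and 1 array, and larger noise in that array or an error of the probe set stays open.

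Myc was 2.03-fold lower in the combination than in the JQ1 array. Yet the 51 measured genes of its target list, Myc included, had a median of 0.03. Over those with agreeing probe sets, at most 26 genes, it was -0.12. Too little room above background does not account for this, since 1 of the 51 targets lay below the signal floor or within 1 log2 unit above it in the JQ1 array. The lowest median over 3 other normalizations, 0.024, decides nothing despite the bound set beforehand. They moved 0 of the 123 named ratios beyond the spread and 8 of 615 list medians. The 42 spikes had a median of -0.065 (SD 0.154), which argues against a shift that hides a median of -0.5 at equal RNA input. Spikes added to equal amounts of RNA cannot show a change common to nearly all transcripts of the cells, so that stays open. A delay between Myc and its targets at 6 hours, or targets held by other factors, was not tested. Myc itself rests on 1 probe set past the floor, so an error in its single ratio stays open.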

How the results depend on the processing

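None of the alternatives listed in the processing part was chosen after the results were seen. Probe sets without a single listed gene, also given below, are not among those alternatives. No paired analysis was possible because each condition has 1 array and no replicate numbers are shared; for the same reason no array could be left out in turn. Median centring, quantile normalization and cyclic loess left each of the 9 counts within 1.5 times of the reported one, and the median ratio of all genes stayed within 0.04 of 0. The counts follow in the order JQ1, SAHA and combination against vehicle, combination against JQ1 and against SAHA, JQ1 in both pairs, SAHA in both pairs, JQ1 and SAHA, and distance from the sum. A threshold of 1.5-fold gave 2968, 2982, 4496, 2265, 2486, 1521, 1313, 1258 and 1855 genes, and 3-fold gave 393, 238, 920, 156, 303, 164, 48, 77 and 71. Requiring agreeing probe sets gave 358, 276, 754, 155, 233, 149, 69, 98 and 100. They come from 4309 genes with at least 2 probe sets past the floor, in place of 10641. Genes whose probe sets disagreed in a comparison were left out of it, so fewer than 4309 genes may have entered each count. The floor at the 75th percentile, with 7148 genes, gave 443 for the combination against JQ1, 621 against SAHA and 279 for the sum. The larger share of higher genes in the combination against JQ1 (432 and 250 lower) was 78 and 77 with agreeing probe sets, 238 and 205 under that floor, and 156 and 182 for probe sets without a single listed gene. The excess also changed side in the combination against vehicle at 3-fold (457 and 463) and for probe sets without a single listed gene (541 and 656). It did so for JQ1 and SAHA with the mean of probe sets (135 and 141) and for the sum at 1.5-fold (931 and 924). For SAHA against vehicle, probe sets without a single listed gene gave 241 higher and 229 lower, against 636 and 397 of the 10641 genes. Of list medians in the outer 5% of their random lists, 5 changed sign with agreeing probe sets: HDAC genes in the combination against JQ1 (-0.52), HDAC inhibitor induced genes (-0.30), immediate early genes (0.48) and fatty acid synthesis (-0.034) in the combination against SAHA, and interferon-stimulated genes with JQ1 (0.089). Under the 75th-percentile floor, NF-kB and inflammatory genes with JQ1 (0.089) and interferon-stimulated genes with the combination (0.043) did so. The sign changes with agreeing probe sets rest on at most 2 HDAC, 11 HDAC inhibitor induced, 6 immediate early, 10 fatty acid synthesis and 3 interferon-stimulated genes. Counting medians closer to 0 as well, the sign changed for 29 of 186 medians with agreeing probe sets, 16 of 190 under the 75th-percentile floor, 13 of 205 without a floor, 8 without _s_at or _x_at names, 7 with the mean of probe sets, 6 with cyclic loess, 5 with quantile normalization and 2 with the floor on the mean of the arrays. Among the first were HDAC genes with JQ1 (-0.32), SAHA (-0.56) and the combination (-1.41), IL6-JAK-STAT3 genes with the combination (0.69), immediate early (0.49), TGF-beta (0.66) and p53 genes (0.36) with JQ1, and MYC targets in the combination against JQ1 (-0.12). Under the 75th-percentile floor IL6-JAK-STAT3 genes with the combination stood at 0.61 against vehicle and 0.21 against SAHA, and interferon-stimulated genes at 0.21 against SAHA. Agreeing probe sets and the higher floor test fewer genes (2 of 9 HDAC genes have at least 2 probe sets past the floor). The rule of agreeing probe sets also takes the mean of a gene's probe sets and leaves out genes with ratios near 0 more often. Beyond that the cause of the sign changes was not tested. Alternatives for single genes were run on 123 named ratios, of ranked genes and genes fixed by name, and not on other list members. Among these no ratio of 2-fold or more changed sign. The smaller ratios of Cdkn1b with the combination, Brd3 with SAHA and Hdac2 with JQ1 did so with the mean of probe sets (-0.14, -0.14 and -0.031), and that of Brd3 with 2 normalizations too. Of the 123 values 41 moved with the mean of probe sets, 31 of the 54 available with agreeing probe sets and 5 without _s_at or _x_at names. Signal over background limits genes near the floor.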

Other observations

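No hypothesis is tested in this part, and the genes of this paragraph outside the naming rule were chosen after their values were seen. Among genes lower in the combination array than in all 3 others, Mir100hg lay furthest below the next array, followed among others by Smim3 and Palmd at 2.05 log2 units each, Serpinb6b at 2.04 and Grem1, which encodes a BMP antagonist, at 1.87. Genes of death receptor signalling and of survival were in this group too: Casp8 lay 1.67, Cflar 1.61 and Bcl2l1 1.02 below the next array. Also in it were Hdac7 at 1.58, the urokinase receptor gene Plaur at 1.56, the kinase gene Src at 1.41 and the TGF-beta receptor gene Tgfbr2 at 1.04. In the other direction, beyond the genes already named, the linker histone gene H1f10 lay 1.48, Reck, which encodes a membrane-anchored inhibitor of metalloproteinases, 1.47 and the synaptotagmin gene Syt1 1.33 above the next array. In total 106 genes lay at least 2-fold below and 85 at least 2-fold above the 3 other arrays.

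Several lists fixed beforehand had medians between percentiles 5 and 97 against vehicle for each treatment. The model deletes p53, so values of p53 targets are no direct measure of p53 activity here. The medians for JQ1, SAHA and the combination were -0.04, 0.06 and -0.10 for 22 p53 targets, although Trp53inp1 stood at 2.05 with JQ1 and Phlda3 at -1.61 with the combination. Over the targets with agreeing probe sets, at most 12, the medians were 0.36, 0.42 and 0.32. They were 0.07, 0.18 and -0.28 for 21 genes of IL6-JAK-STAT3 signalling, with Lif at -1.93 with JQ1 and Stat3 at 1.13 with SAHA. For this list the combination's median was 0.69 with agreeing probe sets and 0.61 under the 75th-percentile floor, and that of JQ1 was 0.41 and 0.37 there but -0.21 with the mean of probe sets. The medians were -0.13, 0.17 and 0.27 for 15 TGF-beta response genes, with Ltbp2 at -2.26 and Bambi at 1.61 with the combination. Over those with agreeing probe sets, at most 3 genes, they were 0.66 with JQ1, 0.41 with SAHA and 0.72 with the combination. For 37 oxidative phosphorylation genes the medians were 0.08, 0.10 and 0.13. Fatty acid synthesis had 0.12, 0.15 and 0.26 over 13 genes (0.35 for SAHA with agreeing probe sets), with Elovl6 at -2.06 with JQ1.

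Few markers of other cell types were measured past the signal floor. Past it were 8 of 27 acinar genes (medians -0.04, 0.11 and 0.07, but 0.40, 0.41 and 0.998 for the 1 gene with agreeing probe sets, with Amy1 at 1.93 and Cela1 at -1.03 with JQ1), 3 of 22 islet genes (Pdx1, also active in pancreatic progenitors, at -1.13 with the combination), 2 of 16 leukocyte genes (Cd68 at 1.54 with SAHA), 2 of 16 fibroblast genes (Acta2, also in the mesenchymal list, and Des), 2 of 10 endothelial genes (Egfl7 at 1.82 with the combination) and 1 of 22 germline genes. That gene, Tex15, read 3.82 with vehicle and with JQ1, 5.01 with SAHA and 6.06 with the combination. The Y-linked genes Eif2s3y, Kdm5d and Uty were past the floor in all 4 arrays; Kdm5d was 2.19-fold and Uty 1.74-fold lower in the combination than in the JQ1 array, while Eif2s3y stood at 0.17.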
